A study of Mus musculus with 18 samples.

How the data were processed

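RNA-seq was carried out on cells sorted from mouse E11 AGM tissue and AGM explants with antibodies to CD31 and Kit and with the BRE-GFP reporter, and libraries were made with a SMARTer kit from RNA extracted with mirVana, per the labels' protocols. Each of the 18 deposited tables holds whole-number read counts per gene symbol for 1 library, with no normalization. The submitters' processing notes name TopHat, Cufflinks, HTSeq and the mm10 genome build; versions, the gene annotation and the strand setting are not given in the sources used here. Because the strand setting is not given, counts of overlapping and antisense genes cannot be separated, and reads at more than 1 place were kept apart by the authors per the deposited tables, which lowers the counts of genes with near-identical copies, such as the hemoglobin, stefin and tryptase genes. Lines that name no gene were kept out of library sizes and tests: reads at no annotated feature made up 19.5 to 49.4% (median 35.8%) and ambiguous reads 0.48 to 0.94% of the reads placed once, and alignments that were not unique were counted apart.

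Groups came from the sample titles. The 18 libraries are the combinations of 3 populations, 3 cultures and 2 BRE-GFP fractions, with 1 library per combination. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, Benjamini-Hochberg adjusted p under 0.05) on all 18 libraries together. Genes with at least 0.796 CPM (10 counts at the median library size) in at least 3 libraries were tested, 16231 of 21881 symbols. HPSC, MC and EC were compared within 6 blocks of the same culture and BRE-GFP fraction, BRE-GFP fractions within 9 pairs of the same population and culture, and cultures within 6 blocks of the same population and fraction. Effects within 1 population, the difference of the BRE-GFP effect between populations and that of the cyclopamine effect between fractions came from models with those terms. Residual degrees of freedom were 10 for population and culture comparisons, 8 for the BRE-GFP comparison, 6 within populations and 4 for cyclopamine by BRE-GFP; the common biological coefficient of variation was 0.88 to 0.92 in the models fitted with blocks. With 1 library per combination, no test could use repeat libraries, and each effect is judged against pooled variation between blocks. Means are given with the SD over libraries, fold changes on the log2 scale with the SE of the fit, and a fold against libraries with 0 counts as a lower bound with a floor of 3 counts over the group; bounds of this kind cover counting error only.

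The 31 gene lists were BMP target genes, BMP pathway components, Hedgehog target genes, Hedgehog pathway components, hematopoietic transcription factors, hematopoietic progenitor surface and signaling genes, pan-endothelial genes, arterial endothelial genes, venous endothelial genes, Notch target genes, VEGF ligands and receptors, mesenchymal genes, smooth muscle genes, extracellular matrix genes, erythroid genes, myeloid and macrophage genes, megakaryocyte genes, mast cell genes, lymphoid genes, germ cell genes, sympathetic neural crest genes, urogenital epithelium genes, sex-linked expression markers, cell cycle genes, glycolysis and hypoxia genes, cholesterol biosynthesis genes, interferon response genes, inflammatory genes, immediate early and heat shock genes, unfolded protein and amino acid response genes and p53 target genes. They were tested against all other genes with camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison; lists with fewer than 4 tested genes were left out. A list score is the mean log2 CPM of its genes in a library. The lists share few genes: 2 of the pan-endothelial, 4 of the arterial, 2 of the venous, 2 of the Notch target and 6 of the VEGF genes stand in another list, and 3 erythroid symbols were not matched. Genes were named by a fixed rule: per comparison over all populations up to 12 higher and 12 lower genes with an adjusted p under 0.05, a mean of at least 10 CPM in 1 group and the same direction in every block, by size of the log2 fold change; within 1 population up to 6 each way; for the tests of differences the 6 of lowest p. Where fewer than 3 genes passed in a direction, the 3 of lowest p with a mean of at least 10 CPM were named as not passing, and members of lists, Pecam1 and Kit were named beside their list or gate. Predicted genes and small RNAs were skipped, and the values of some genes that the rule names are not reported here. Single libraries were compared by log2 ratios of CPM + 5, with up to 6 genes each way among those with at least 50 counts and 20 CPM in 1 of the 2 libraries, and list medians were set against 10000 random lists of the same size matched on mean expression. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names, in which 19570 of 21881 symbols have 1 gene of the same name, and cover the whole gene on the stated strand.

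The design, the lists, the naming rule and the alternatives were chosen before the data were examined, except for 9 additions made after the data were seen and the tests that the closing part names as chosen after the result was seen. The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no expression filter, the CPM minimum in 6 libraries, robust empirical Bayes, an additive model, the libraries of 1 population or fraction alone, each library left out in turn, an estimated correlation or prior count 0.5 in camera, and for single libraries a pseudocount of 1 CPM or no TMM scaling. The additions were a fit without the library of fewest detected genes of each population, the share of reads at no annotated feature as a covariate, an exact sign-flip test of list scores, a camera test of differences of the BRE-GFP effect between populations, list score differences with 1 block and differences between populations with 1 culture left out, and tests of Hedgehog target genes in MC and of other cell types in HPSC and EC apart, also with 1 pair left out. The fits were tested on simulated counts with 200 of 16231 genes changed, drawn with the trended dispersion of the BRE-GFP model and no block effects. At log2 changes of 2, 3, 4 and 5, edgeR recovered 46, 78, 90 and 94% of changed genes for HPSC against EC. Explant gave 34, 68, 80 and 96% and cyclopamine 38, 64, 82 and 96%. BRE-GFP within HPSC gave 16, 46, 58 and 80% and cyclopamine by BRE-GFP 4, 6, 30 and 58%. False calls numbered 0 to 4. In each of 5 simulated comparisons camera called the list moved by a log2 change of 1 and 0 of 30 unmoved lists. This did not test the preset correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.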

Results

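RNA was sequenced from cells sorted out of the aorta-gonad-mesonephros (AGM) region of mouse embryos at embryonic day 11, a region in which hematopoietic stem cells first arise. The embryos carried BRE-GFP, a reporter in which a BMP-responsive element drives green fluorescent protein, so that GFP marks cells with a transcriptional response to BMP. Endothelial-enriched cells (EC) were CD31 positive and Kit negative, cells enriched for hematopoietic progenitors and stem cells (HPSC) were positive for both, and mesenchymal-enriched cells (MC) were negative for both. Each of these 3 populations was taken from fresh AGM, from explants cultured with BMP and Hedgehog, and from such explants treated with cyclopamine, an inhibitor of the Hedgehog signal transducer Smoothened. Each was further divided into BRE-GFP positive and negative cells, which gave 18 combinations with 1 library each. The design asks how BMP-responding cells differ from non-responding ones, and how culture and blocked Hedgehog signalling alter each population. Libraries are named by population, culture and BRE-GFP fraction, so that EC explant negative is the library of BRE-GFP negative EC from the explant without cyclopamine. Counts assigned to genes ranged from 3041249 (HPSC cyclopamine negative) to 21972063 (MC cyclopamine positive) per library. No combination had a repeat library, so the error of every test is the variation of effects between blocks of matched libraries, pooled over all 18 libraries. Nothing in the labels says whether matched libraries came from separate embryos or sorts. The p-values therefore measure the spread between these libraries only, part of which may be technical.

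The sort markers followed the gates. Pecam1, which encodes CD31 (chromosome 11, 106654217 to 106750628, minus strand), stood at 93.7 to 2682 CPM (counts relative to the TMM-scaled library total) in the 12 EC and HPSC libraries and at 3.0 to 11.5 CPM in the 6 MC libraries. Kit (chromosome 5, 75574916 to 75656722, plus strand) stood at 449.9 to 1135 CPM in HPSC and at 20.9 to 219.9 CPM in EC and MC. Between 10297 (HPSC cyclopamine negative) and 18816 (MC explant positive) of the 21881 gene symbols had at least 1 count. Reads at no annotated feature made up 21.7 to 42.0% in fresh, 35.0 to 49.4% in explant and 19.5 to 33.0% in cyclopamine libraries. Spearman correlations of log2 CPM between libraries, across genes, ran from 0.656 to 0.973 (median 0.862 within and 0.809 between populations).

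**Figure D1:**
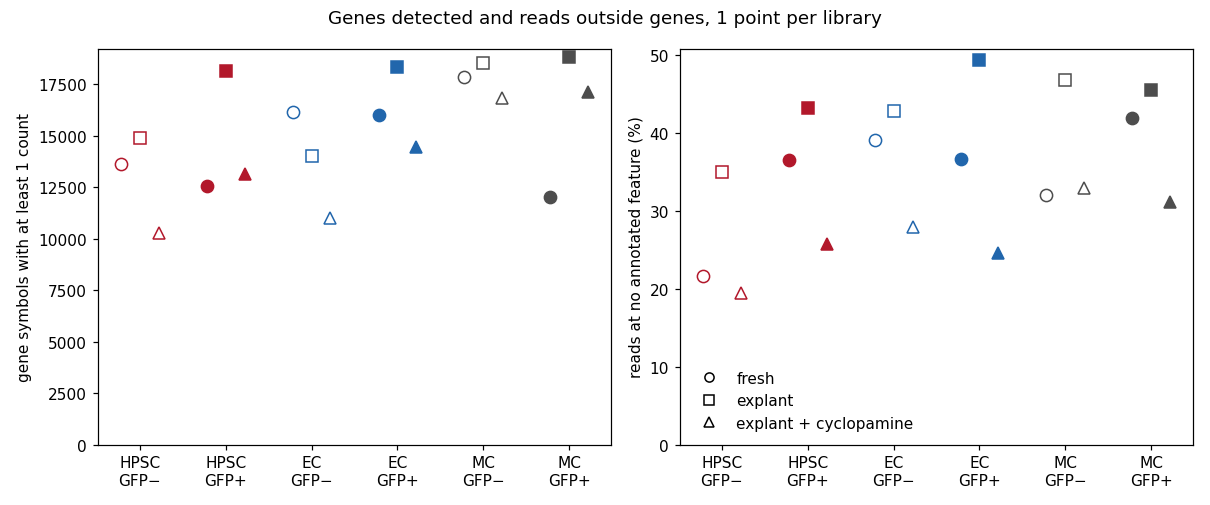
The left panel shows the number of gene symbols with at least 1 count and the right panel the share of reads at no annotated feature in percent, 1 point per library, by population and BRE-GFP fraction. Circles are fresh AGM, squares explants, triangles explants with cyclopamine and filled symbols BRE-GFP positive, and in each of the 6 groups the cyclopamine library lies below the explant library in both panels.

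HPSC carried more of the transcripts of blood progenitors than EC and fewer of those of mesenchyme and platelets. Hlf, a transcription factor of hematopoietic stem cells (chromosome 11, 90336536 to 90390895, minus strand), averaged 46.7 ± 20.9 against 1.99 ± 2.25 CPM (mean ± SD, n = 6 libraries each, HPSC first; log2 fold change 5.21 ± 0.93 (SE), edgeR adjusted p = 0.0306). Mpo, the myeloperoxidase of granulocyte precursors, averaged 3883 ± 3329 against 594 ± 561 CPM (edgeR adjusted p = 0.0291). Agtr2, an angiotensin receptor (chromosome X, 21484544 to 21489164, plus strand), had the lowest p on the EC side, at 6.55 ± 7.64 against 226 ± 183 CPM (log2 fold change -5.05 ± 0.59 (SE), edgeR adjusted p = 0.00253). In all, 52 of 16231 tested genes passed, 6 higher and 46 lower in HPSC, with 1512 at an unadjusted p under 0.05. The other named higher genes were Car2 (log2 fold change 2.85) and Gpr56 (1.91), an adhesion receptor. The named lower genes held the cartilage matrix genes Matn3 and Lect1, the collagen crosslinking enzyme gene Lox, the fibroblast protease gene Fap, the muscle regulator Myog and the platelet tubulin gene Tubb1. With Moxd1, Ltf, Zcchc5, Nlgn3 and Agtr2, their log2 fold changes ran from -7.46 to -4.99. Best1 also fell, with a mean of 0.0355 ± 0.0576 CPM in HPSC and 11.2 ± 16.1 CPM in EC.

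Gene lists set HPSC apart from EC in the same sense, with score differences in mean log2 CPM (HPSC minus EC, mean ± SD over 6 blocks). Mesenchymal genes differed by -2.05 ± 1.0, lower in 6 of 6 blocks (camera adjusted p = 8.88e-11). Of the 18 mesenchymal genes, 5 passed over all genes and 11 adjusted over the list alone (adjusted p = 0.0378 with an estimated correlation). Pdgfra, Pdgfrb, Col1a1, Dcn and Lum, all genes of fibroblasts and their matrix, were the members that fell over all genes. Megakaryocyte genes differed by -2.99 ± 1.25, lower in 6 of 6 blocks (camera adjusted p = 1.60e-07). Of the 10 megakaryocyte genes, 1 passed over all genes and 8 adjusted over the list alone (adjusted p = 0.0378 with an estimated correlation). The platelet chemokine gene Ppbp fell (log2 fold change -4.59). BMP target genes differed by -1.60 ± 0.39, lower in 6 of 6 blocks (camera adjusted p = 4.32e-05). Of the 16 BMP target genes, 1 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.0225 with an estimated correlation). The member that fell was Bmper, a secreted BMP-binding protein (chromosome 9, 23223076 to 23485200, plus strand; log2 fold change -3.62 ± 0.66 (SE), edgeR adjusted p = 0.0306). Id1 and Id3, both induced by BMP, stood at 17.7 ± 9.75 against 39.7 ± 15.8 CPM and 217 ± 68.4 against 391 ± 179.9 CPM and did not pass. Hedgehog pathway components differed by -1.41 ± 0.59, lower in 6 of 6 blocks (camera adjusted p = 8.30e-04). Of the 14 Hedgehog pathway components, 1 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.0378 with an estimated correlation). The coreceptor gene Boc fell (log2 fold change -4.01). Mast cell genes were higher in HPSC by 2.21 ± 1.27, higher in 6 of 6 blocks (camera adjusted p = 4.12e-06). Of the 9 mast cell genes, 1 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.0225 with an estimated correlation). Tpsb2 rose (log2 fold change 7.63), and its reads may be shared with related tryptase genes. Hematopoietic transcription factors were higher by 1.60 ± 1.08, higher in 6 of 6 blocks (camera adjusted p = 2.06e-09). Of the 20 hematopoietic transcription factors, 1 passed over all genes and 3 adjusted over the list alone (adjusted p = 0.0643 with an estimated correlation). Myb, a regulator of definitive hematopoiesis, averaged 109 ± 52.9 against 8.78 ± 13.8 CPM. Progenitor surface and signaling genes were higher by 1.22 ± 1.14, higher in 5 of 6 blocks (camera adjusted p = 1.21e-09). Of the 20 progenitor surface and signaling genes, 0 passed over all genes and 8 adjusted over the list alone, 7 up and 1 down (adjusted p = 0.0643 with an estimated correlation). The cytokine receptor gene Flt3 averaged 74.1 ± 50.96 against 5.73 ± 6.87 CPM.

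Further lists were called between HPSC and EC and not with an estimated correlation. Extracellular matrix genes were lower in HPSC (camera adjusted p = 1.69e-06). Of the 16 matrix genes, 1 passed over all genes and 8 adjusted over the list alone (adjusted p = 0.0526 with an estimated correlation). Cell cycle genes were higher by 0.32 ± 0.20, higher in 6 of 6 blocks (camera adjusted p = 4.49e-04). Of the 20 cell cycle genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.0526 with an estimated correlation). Erythroid genes were higher (camera adjusted p = 4.85e-05). Of the 12 erythroid genes, 0 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.193 with an estimated correlation). Myeloid genes were higher (camera adjusted p = 5.52e-04). Of the 18 myeloid genes, 1 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.287 with an estimated correlation). Glycolysis and hypoxia genes were higher (camera adjusted p = 7.02e-05). Of the 17 glycolysis genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.114 with an estimated correlation). BMP pathway components were lower, a call that ended at 0.070 without EC explant negative (camera adjusted p = 0.0131). Of the 16 BMP pathway components, 0 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). Hedgehog target genes (camera adjusted p = 0.185), pan-endothelial genes (0.306), arterial genes (0.993) and Notch target genes (0.0784) were not called. Neither were p53 target genes (0.23) and sex-linked markers (0.787). DESeq2 called 795 genes between HPSC and EC and limma-voom 570. EdgeR called 5 with the share of reads at no annotated feature as a covariate and 32 without the library of fewest detected genes of each population. With 1 library left out, the count was 1 without EC explant negative, EC explant positive, HPSC cyclopamine positive, HPSC explant negative or MC explant negative, 2 without EC cyclopamine positive, 6 without HPSC cyclopamine negative, 8 without MC explant positive, 15 without HPSC explant positive, 16 without HPSC fresh positive, 17 without EC cyclopamine negative, 28 without MC cyclopamine positive and 31 without MC fresh negative. Agtr2 passed in 18 of 18 such fits (highest adjusted p = 0.0249 without HPSC cyclopamine positive) and Mpo in 12 of 18 (0.0856 without HPSC cyclopamine positive). Hlf passed in 9 of 18 (0.0984 without EC cyclopamine positive) and Tubb1 in 0 of 18 (0.146 without EC explant positive).

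MC libraries held fewer transcripts of endothelium, macrophages and platelets than EC libraries and more of sympathetic neurons. Prg2, an eosinophil granule protein (chromosome 2, 84980461 to 84983632, plus strand), averaged 0.844 ± 0.871 against 529 ± 619 CPM (MC first, n = 6 libraries each; log2 fold change -8.75 ± 1.05 (SE), edgeR adjusted p = 7.90e-05). Of 16231 genes, 413 passed, 42 higher and 371 lower in MC (1854 at an unadjusted p under 0.05). The named higher genes were neuronal apart from Serinc2, and included Dbh, which encodes the enzyme that makes noradrenaline (83.5 ± 64.2 against 9.58 ± 13.2 CPM), and the neuronal tubulin gene Tubb3 (154 ± 59.8 against 23.2 ± 21.2 CPM). The others were the neurofilament genes Nefl and Nefm, and Elavl4, Scg5, Chrna4, Cacng3, Nap1l2 and Ndst3. The named lower genes were led by the platelet genes Gp1ba, Gp9, Tubb1, Gp6, Ppbp, Clec1b, P2ry12 and F2rl2, with log2 fold changes from -8.31 to -6.77. They also held the leukocyte activation marker Cd69 and the collagenase gene Mmp13.

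Pan-endothelial genes differed between MC and EC by -4.14 ± 1.69 in mean log2 CPM (MC minus EC, 6 blocks), lower in 6 of 6 (camera adjusted p = 2.69e-25). Of the 18 pan-endothelial genes, 11 passed over all genes and 15 adjusted over the list alone (adjusted p = 0.038 with an estimated correlation). Cdh5, the endothelial cadherin gene, stood at 2.68 ± 1.28 against 273 ± 274 CPM. Myeloid genes differed by -4.24 ± 1.03, lower in 6 of 6 blocks (camera adjusted p = 1.07e-34). Of the 18 myeloid genes, 16 passed over all genes and 17 adjusted over the list alone (adjusted p = 0.00703 with an estimated correlation). Csf1r, Cx3cr1, Itgam, C1qa and Lyz2, all macrophage genes, fell with log2 fold changes from -5.61 to -4.22. Megakaryocyte genes were lower in MC (camera adjusted p = 2.44e-19). Of the 10 megakaryocyte genes, 8 passed over all genes and 9 adjusted over the list alone (adjusted p = 0.00373 with an estimated correlation). Progenitor surface and signaling genes were lower (camera adjusted p = 5.29e-28). Of the 20 progenitor surface and signaling genes, 14 passed over all genes and 17 adjusted over the list alone, 1 of them up (adjusted p = 0.00703 with an estimated correlation). Sympathetic neural crest genes were higher by 3.08 ± 1.26, higher in 6 of 6 blocks (camera adjusted p = 1.73e-10). Of the 13 neural crest genes, 4 passed over all genes and 10 adjusted over the list alone (adjusted p = 0.0411 with an estimated correlation). Erythroid genes were higher in MC by 2.26 ± 2.92, higher in 5 of 6 blocks (camera adjusted p = 0.0013). Of the 12 erythroid genes, 0 passed over all genes and 3 adjusted over the list alone (adjusted p = 0.257 with an estimated correlation). Arterial genes were lower (camera adjusted p = 3.40e-09). Of the 16 arterial genes, 5 passed over all genes and 6 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Smooth muscle genes were higher (camera adjusted p = 3.73e-05). Of the 11 smooth muscle genes, 1 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). The actin gene Acta2 rose (log2 fold change 1.97). Germ cell genes were lower (camera adjusted p = 5.16e-06). Of the 13 germ cell genes, 3 passed over all genes and 6 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Dppa3 and Dazl, both germ cell genes, fell (log2 fold changes -6.37 and -4.90). Inflammatory genes were lower (camera adjusted p = 2.37e-10). Of the 15 inflammatory genes, 5 passed over all genes and 6 adjusted over the list alone (adjusted p = 0.0688 with an estimated correlation). Interferon response genes were lower as well (camera adjusted p = 8.36e-07). Of the 16 interferon response genes, 3 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.159 with an estimated correlation). Hedgehog target genes were higher by 1.26 ± 1.11, higher in 6 of 6 blocks, a call that ended at 0.0582 without MC fresh negative (camera adjusted p = 0.0186). Of the 11 Hedgehog target genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.118 with an estimated correlation). Gli1, a transcription factor induced by Hedgehog, averaged 30.5 ± 7.79 against 9.03 ± 12.2 CPM. DESeq2 called 1246 genes between MC and EC and limma-voom 1932, and the count was 258 without EC fresh negative. Prg2, Gp1ba, Gp9, Tubb1, Gp6, Ppbp, Clec1b, Cd69 and F2rl2 passed in 18 of 18 fits with 1 library left out. Tubb3 passed in 17 of 18 (highest adjusted p = 0.0656 without MC fresh positive) and Dbh in 16 of 18 (0.0637 without MC fresh positive).

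**Figure D2:**
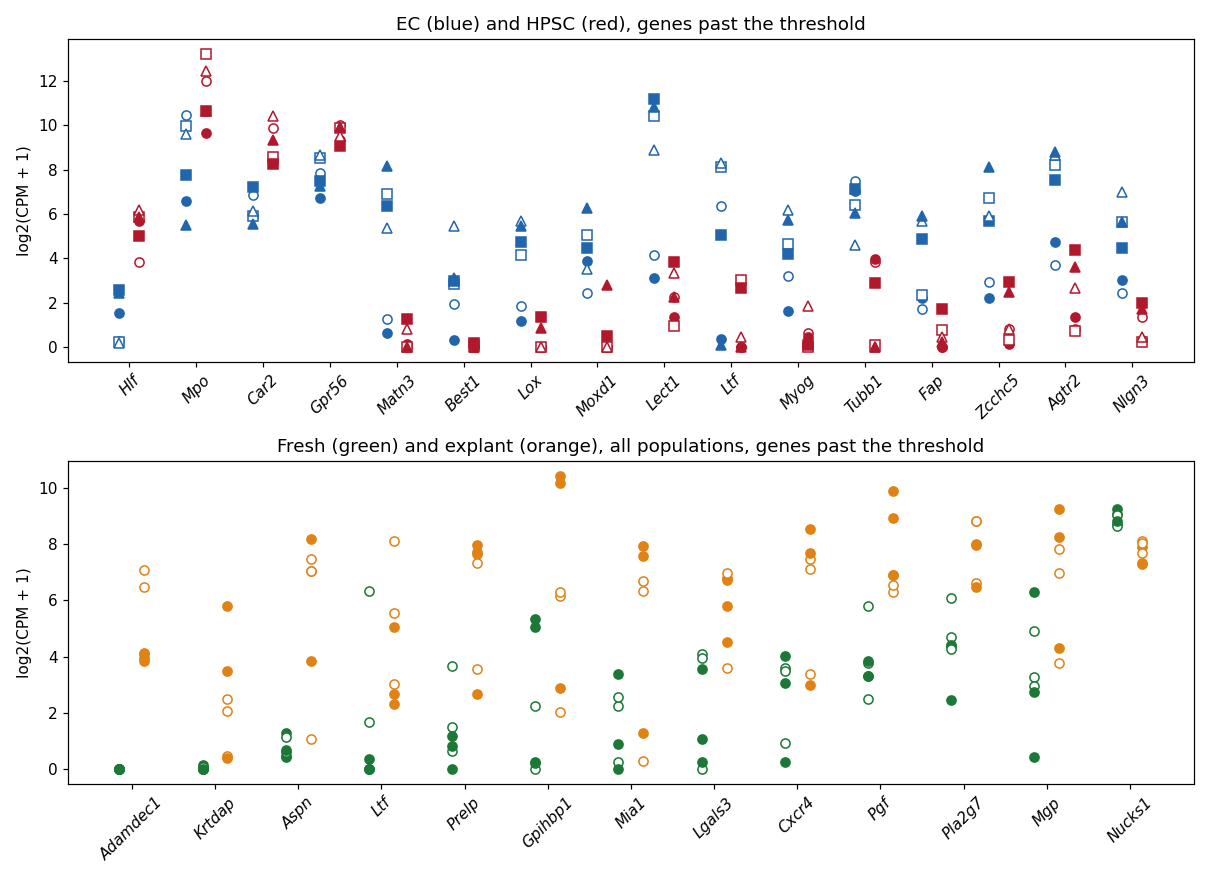
Each point is the log2(CPM + 1) of 1 library for a named gene that passed, in the upper panel for EC (blue) and HPSC (red) and in the lower panel for fresh (green) and explant (orange) libraries of all populations; filled symbols are BRE-GFP positive, and in the upper panel circles are fresh, squares explant and triangles cyclopamine libraries. Agtr2 averaged 226 ± 183 CPM in EC and 6.55 ± 7.64 CPM in HPSC, and Cxcr4 averaged 7.55 ± 6.02 CPM in fresh and 151 ± 137 CPM in explant libraries.

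S100a9, Camp and Pglyrp1 were lower in BRE-GFP positive than in negative cells of the same population and culture, and Pea15a was higher. S100a9, a calcium-binding protein of neutrophils (chromosome 3, 90692632 to 90695721, minus strand), averaged 9.21 ± 18.7 against 131 ± 129 CPM (positive first, n = 9 libraries each; log2 fold change -5.57 ± 0.91 (SE), edgeR adjusted p = 0.0432). The granulocyte genes Camp and Pglyrp1 averaged 3.27 ± 5.77 against 55.2 ± 76.4 CPM and 6.35 ± 7.78 against 56.9 ± 59.4 CPM (edgeR adjusted p = 0.0432 for both). Pea15a, an adaptor protein of ERK signalling (chromosome 1, 172196728 to 172206804, minus strand), was higher, at 363 ± 190.4 against 118 ± 35.5 CPM (log2 fold change 1.51 ± 0.24 (SE), edgeR adjusted p = 0.0432). In all, 9 genes passed, 1 higher and 8 lower (860 at an unadjusted p under 0.05). The other named lower genes were Stfa1, whose reads may be shared with near-identical stefin genes, the leukocyte GTPase gene Rac2, the proteoglycan gene Srgn and the transferrin receptor gene Tfrc, at log2 fold changes from -4.43 to -1.28. With 1 library left out, S100a9 and Pglyrp1 passed in 0 of 18 fits, Camp in 2 and Pea15a in 4 (highest adjusted p = 0.216, 0.228, 0.266 and 0.175 without EC fresh negative). Cd34, Igf2 and Sparc had the lowest p among higher genes that missed the threshold (edgeR adjusted p = 0.0833, 0.0866 and 0.0866).

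Pan-endothelial genes were higher in BRE-GFP positive libraries by 2.23 ± 1.97 in mean log2 CPM (mean ± SD over 9 pairs), higher in 7 of 9 (camera adjusted p = 3.52e-13). Of the 18 pan-endothelial genes, 0 passed over all genes and 13 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). Kdr, the main VEGF receptor, averaged 396 ± 406 against 53.6 ± 58.4 CPM and the endothelial sialomucin gene Emcn 483 ± 449.8 against 65.4 ± 77.1 CPM. Arterial genes were higher (camera adjusted p = 4.50e-07). Of the 16 arterial genes, 0 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.189 with an estimated correlation). Venous genes were higher (camera adjusted p = 1.56e-04). Of the 8 venous genes, 0 passed over all genes and 3 adjusted over the list alone (adjusted p = 0.189 with an estimated correlation). VEGF ligands and receptors were higher (camera adjusted p = 2.46e-04). Of the 10 VEGF ligands and receptors, 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). Extracellular matrix genes were higher in 9 of 9 pairs, by 0.88 ± 0.54 (camera adjusted p = 7.52e-05). Of the 16 matrix genes, 0 passed over all genes and 3 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). Myeloid genes were lower (camera adjusted p = 2.33e-09). Of the 18 myeloid genes, 0 passed over all genes and 6 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). Erythroid genes differed by -1.27 ± 2.31, and by -0.65 without the fresh MC pair (camera adjusted p = 9.18e-07). Of the 12 erythroid genes, 1 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.189 with an estimated correlation). Cell cycle genes differed by -0.26 ± 0.27, lower in 8 of 9 pairs (camera adjusted p = 2.09e-04). Of the 20 cell cycle genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). Progenitor surface and signaling genes were lower (camera adjusted p = 5.20e-04). Of the 20 progenitor surface and signaling genes, 1 passed over all genes and 10 adjusted over the list alone, 8 down and 2 up (adjusted p = 0.209 with an estimated correlation).

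Germ cell genes differed between BRE-GFP positive and negative libraries by -2.12 ± 1.94, lower in 8 of 9 pairs (camera adjusted p = 1.12e-11). Of the 13 germ cell genes, 0 passed over all genes and 8 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). Dazl averaged 8.79 ± 13.8 against 112 ± 149 CPM. Sympathetic neural crest genes were higher by 1.21 ± 1.38, higher in 8 of 9 pairs (camera adjusted p = 3.64e-04). Of the 13 neural crest genes, 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.242 with an estimated correlation). BMP target genes were not called (camera adjusted p = 0.376) and differed by 0.39 ± 0.85 (0.25 without the cyclopamine EC pair), higher in all 6 cultured and lower in all 3 fresh pairs. Of the 16 BMP target genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.572 with an estimated correlation). Among the BMP-induced genes, the log2 fold changes were -0.04 for Id1, -0.48 for Id2, 0.62 for Id3 and 0.66 for Smad6. Lymphoid genes (camera adjusted p = 0.566) and urogenital epithelium genes (0.681) were not called either. Notch target genes were higher (camera adjusted p = 0.0151). Of the 7 Notch target genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). The Notch call ended at 0.0657 without HPSC explant negative, 0.0646 without HPSC explant positive, 0.105 without MC fresh negative and 0.108 without MC fresh positive. Immediate early and heat shock genes were higher (camera adjusted p = 0.0143). Of the 15 immediate early genes, 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.264 with an estimated correlation). The immediate early call ended at 0.105 without MC fresh negative, 0.108 without MC fresh positive, 0.0596 without MC cyclopamine negative, 0.0606 without MC cyclopamine positive, 0.0688 without MC explant negative and 0.0685 without MC explant positive. No gene passed under every library left out. The edgeR count was 0 without any 1 of the 12 EC and HPSC libraries (520 to 1023 genes at an unadjusted p under 0.05), 1 without either fresh MC library, 2 without either cyclopamine MC library and 6 without either explant MC library. DESeq2 called 371 genes between the fractions and limma-voom 202. With the share of reads at no annotated feature as a covariate, or without the library of fewest genes of each population, edgeR called 0 genes (299 and 1391 at an unadjusted p under 0.05).

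**Figure D3:**
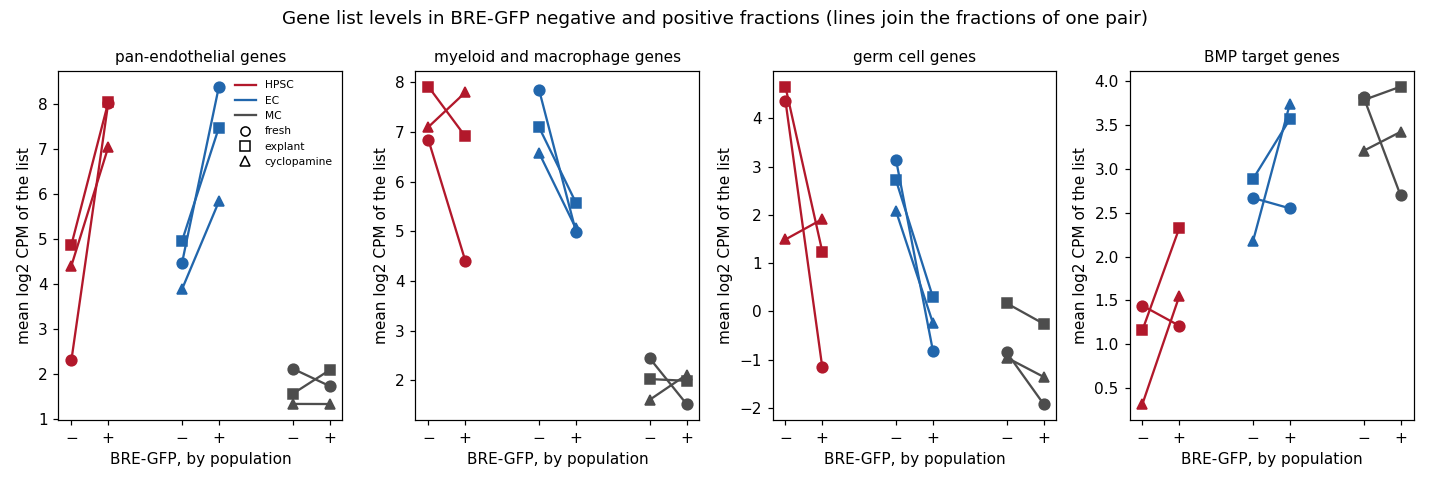
The y axis is the mean log2 CPM of the genes of a list and each line joins the BRE-GFP negative and positive library of 1 population and culture, for pan-endothelial, myeloid, germ cell and BMP target genes from left to right. Red is HPSC, blue EC and grey MC, circles are fresh, squares explant and triangles cyclopamine libraries, and the pan-endothelial lines rise in all 6 HPSC and EC pairs, by 3.32 ± 1.35 on average.

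Within HPSC, 6 genes passed between the BRE-GFP fractions, all higher in the positive one (1234 at an unadjusted p under 0.05). Clec1a, a C-type lectin receptor (chromosome 6, 129424772 to 129452000, minus strand), averaged 81.8 ± 33.4 against 0.053 ± 0.0918 CPM (positive first, n = 3 libraries each; edgeR adjusted p = 0.0416). Klhl4 averaged 532 ± 479.6 against 12.1 ± 3.03 CPM (log2 fold change 5.11 ± 0.68 (SE), edgeR adjusted p = 0.0358). Arhgap31, the matrix genes Bgn and Nid1, and the imprinted gene Mest were the others, and log2 fold changes beside Clec1a ran from 2.45 to 5.11. Mpo, at 1347 ± 465 against 6419 ± 2862 CPM, was among the lower genes of lowest p and did not pass (edgeR adjusted p = 0.117). Pan-endothelial genes were higher in 3 of 3 pairs, by 3.84 ± 1.65 (camera adjusted p = 5.43e-13). Of the 18 pan-endothelial genes, 0 passed over all genes and 17 adjusted over the list alone (adjusted p = 0.0918 with an estimated correlation). Kdr averaged 630.5 ± 333 against 34.4 ± 35.4 CPM and Sox7, an endothelial transcription factor, 174 ± 28.2 against 8.4 ± 13.2 CPM. Arterial genes were higher in this fraction (camera adjusted p = 7.10e-08). Of the 16 arterial genes, 0 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.0815 with an estimated correlation). Venous genes were higher too (camera adjusted p = 1.67e-05). Of the 8 venous genes, 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.0815 with an estimated correlation). VEGF ligands and receptors were also higher (camera adjusted p = 1.90e-04). Of the 10 VEGF ligands and receptors, 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.0815 with an estimated correlation). Germ cell genes differed by -2.84 ± 3.02, lower in 2 of 3 pairs, by -1.50 without the fresh and by -4.48 without the cyclopamine pair (camera adjusted p = 5.16e-08). Of the 13 germ cell genes, 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.235 with an estimated correlation). DESeq2 called 929 genes in HPSC, limma-voom 136 and edgeR without an expression filter 96. EdgeR called 0 with any 1 HPSC library left out (993 to 1429 at an unadjusted p under 0.05), and the highest adjusted p of Klhl4 was 0.313 without HPSC fresh positive. It also called 0 with the HPSC libraries alone (579 at an unadjusted p under 0.05). Without the library of fewest genes of each population, edgeR called 10 genes, of which 0 were among the 6.

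Within EC, Cd34, a surface sialomucin of endothelium and progenitors (chromosome 1, 194938819 to 194961279, plus strand), was higher in the BRE-GFP positive fraction at 700.0 ± 498 against 118 ± 49.8 CPM (n = 3 libraries each; log2 fold change 2.42 ± 0.34 (SE), edgeR adjusted p = 0.0489). Mpo (chromosome 11, 87793581 to 87804413, plus strand) was lower at 119 ± 89.1 against 1069 ± 319 CPM (log2 fold change -3.43 ± 0.48 (SE), edgeR adjusted p = 0.0489). No other gene passed in EC (696 at an unadjusted p under 0.05). Pan-endothelial genes were higher in 3 of 3 EC pairs, by 2.79 ± 1.01 (camera adjusted p = 4.84e-09). Of the 18 pan-endothelial genes, 0 passed over all genes and 12 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). Myeloid genes were lower in positive EC (camera adjusted p = 4.82e-14). Of the 18 myeloid genes, 1 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). Germ cell genes were lower there as well (camera adjusted p = 8.27e-12). Of the 13 germ cell genes, 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). DESeq2 called 426 genes in EC and limma-voom 3. With 1 EC library left out, Cd34 passed in 0 of 6 fits and Mpo in 2 (highest adjusted p of both = 0.895 without EC cyclopamine positive). EdgeR called 0 without either fresh or either cyclopamine EC library (497 to 858 at an unadjusted p under 0.05). It called 0 with the EC libraries alone (475), with the CPM minimum in 6 libraries (673) and without the library of fewest genes of each population (1229).

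In MC, edgeR called 0 genes between the BRE-GFP fractions (70 at an unadjusted p under 0.05), DESeq2 5 and limma-voom 102. Car2, a carbonic anhydrase of red cells, averaged 202 ± 194 against 896 ± 190.3 CPM and the erythroid regulator Gata1 8.49 ± 8.05 against 40.3 ± 20.5 CPM without passing. Erythroid genes differed in MC by -2.62 ± 3.18, lower in 3 of 3 pairs, and by -0.80 without the fresh pair (camera adjusted p = 4.03e-08). Of the 12 erythroid genes, 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.278 with an estimated correlation). Sympathetic neural crest genes were higher in 3 of 3 MC pairs, by 1.24 ± 1.15, and by 0.67 without the fresh pair (camera adjusted p = 4.03e-08). Of the 13 neural crest genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.252 with an estimated correlation). The test of whether the BRE-GFP effect differed between the 3 populations called 0 genes by edgeR (369 at an unadjusted p under 0.05), 49 by DESeq2 and 2 by limma-voom. A gene that passed in 1 population is therefore not shown to differ from the others. Klhl4, Clec1a, Arhgap31, Bgn, Nid1 and Plk2 had the lowest p in that test.

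Explant libraries held more Cxcr4, Pla2g7 and Adamdec1 than fresh libraries, in 6 of 6 blocks over the 3 populations. Cxcr4, the chemokine receptor for Cxcl12 (chromosome 1, 128588199 to 128592293, minus strand), averaged 151 ± 137 against 7.55 ± 6.02 CPM (explant first, n = 6 libraries each; log2 fold change 4.09 ± 0.47 (SE), edgeR adjusted p = 6.55e-04). Pla2g7, a secreted phospholipase that degrades platelet-activating factor (chromosome 17, 43568098 to 43612201, plus strand), averaged 264 ± 159 against 25.9 ± 21.3 CPM (log2 fold change 3.41 ± 0.39 (SE), edgeR adjusted p = 6.55e-04). Adamdec1, a metalloprotease gene of macrophages (chromosome 14, 68563380 to 68582095, minus strand), averaged 47.2 ± 52.01 CPM and had 0 counts in all 6 fresh libraries. Adamdec1 was thus at least 815-fold higher (edgeR adjusted p = 0.00754, floor of 3 counts over the fresh group). In all, 22 genes passed, 21 higher and 1 lower (1393 at an unadjusted p under 0.05). The matrix genes Aspn, Prelp and Mgp stood at 123 ± 106 against 0.762 ± 0.462 CPM, 139 ± 106 against 2.73 ± 4.53 CPM and 216 ± 224 against 21.3 ± 29.1 CPM. The VEGF family gene Pgf stood at 305 ± 345 against 17.3 ± 18.8 CPM, and the other named higher genes were the lectin gene Lgals3, Gpihbp1, Mia1, Ltf and Krtdap. Nucks1, a chromatin protein, was the gene that fell (217 ± 51.4 against 488 ± 83.6 CPM; log2 fold change -1.18 ± 0.20 (SE), edgeR adjusted p = 0.0359).

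Cell cycle genes were lower in explants in 6 of 6 blocks, differing by -0.66 ± 0.19 in mean log2 CPM (camera adjusted p = 2.72e-10). Among the 20 cell cycle genes, 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.00153 with an estimated correlation). Mki67 and Top2a, both markers of dividing cells, averaged 217 ± 112 against 440.4 ± 64.8 CPM and 644 ± 284 against 1079 ± 277 CPM. Interferon response genes were higher in 6 of 6 blocks, by 2.22 ± 1.44 (camera adjusted p = 5.37e-06). Among the 16 interferon response genes, 0 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.71 with an estimated correlation). Usp18 and Rtp4 averaged 63.3 ± 19.97 against 11.99 ± 11.5 CPM and 91.6 ± 56.97 against 20.1 ± 28.8 CPM. Genes of the unfolded protein and amino acid response were higher by 1.15 ± 0.72 (camera adjusted p = 0.0098). Among the 14 unfolded protein response genes, 0 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.71 with an estimated correlation). The stress regulator Ddit3 averaged 67.5 ± 44.8 against 19.3 ± 4.26 CPM, and the call ended at 0.0554 without EC explant negative and 0.0582 without MC fresh negative. Glycolysis and hypoxia genes were higher, a call that ended at 0.0554 without EC explant negative, 0.0713 without HPSC fresh negative and 0.0671 without MC explant positive (camera adjusted p = 0.0216). Among the 17 glycolysis genes, 0 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.943 with an estimated correlation). Venous genes were lower, a call that ended at 0.0732 without EC fresh positive and 0.0532 without HPSC fresh positive (camera adjusted p = 0.00772). Among the 8 venous genes, 0 passed over all genes and 3 adjusted over the list alone (adjusted p = 0.266 with an estimated correlation). The venous apelin receptor gene Aplnr averaged 53.5 ± 55.8 against 916 ± 1363 CPM. DESeq2 called 484 genes between explant and fresh libraries and limma-voom 1270. EdgeR called 11 with the CPM minimum in 6 libraries, 39 without a filter, 14 in an additive model and 37 without the library of fewest genes of each population. It called 0 with the share of reads at no annotated feature as a covariate (854 at an unadjusted p under 0.05). BRE-GFP positive libraries alone gave 7 genes and negative ones alone 0 (265 at an unadjusted p under 0.05). With 1 library left out, the count was 7 without HPSC explant positive, 8 without EC fresh positive, MC explant positive or MC fresh negative, 9 without EC explant positive or HPSC cyclopamine positive, 10 without EC fresh negative, MC cyclopamine negative, MC explant negative or MC fresh positive, 11 without HPSC fresh positive, 12 without EC explant negative, 14 without EC cyclopamine positive and 39 without HPSC cyclopamine negative. Cxcr4, Pla2g7 and Adamdec1 passed in 18 of these 18 fits, with highest adjusted p of 0.00836 without EC explant positive, 0.00635 without MC fresh positive and 0.0294 without EC explant positive. Aspn passed in 16 of 18 (0.0603 without MC fresh negative).

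Taken 1 population at a time, the explant comparison rested on 2 libraries against 2. In EC, Lrrc17, a secreted leucine-rich repeat protein (chromosome 5, 21543559 to 21575904, plus strand), rose to 265 ± 23.6 CPM from 17.6 ± 0.447 CPM (log2 fold change 3.91 ± 0.50 (SE), edgeR adjusted p = 0.0329) as the single gene that passed (374 at an unadjusted p under 0.05). DESeq2 called 119 genes there, limma-voom 7, edgeR without a filter 31 and edgeR without the library of fewest genes of each population 6. EdgeR called 0 without any 1 of the 6 EC libraries (213 to 572 at an unadjusted p under 0.05), with Lrrc17 at up to 0.879 without EC fresh negative, and 0 with the EC libraries alone (296). In HPSC, edgeR called 0 genes (700 at an unadjusted p under 0.05), DESeq2 275 and limma-voom 15, and edgeR called 1 without HPSC fresh negative and 2 without HPSC cyclopamine negative. Gpnmb averaged 443 ± 59.6 against 3.81 ± 2.01 CPM and Spp1, osteopontin, 265 ± 11.4 against 2.74 ± 3.53 CPM without passing. In MC, edgeR called 0 genes (402 at an unadjusted p under 0.05), DESeq2 66 and limma-voom 13, with Aspn at 209 ± 108 against 0.916 ± 0.448 CPM. Cell cycle genes were lower in 2 of 2 HPSC blocks, differing by -0.69 ± 0.20 (camera adjusted p = 5.39e-06). Among the 20 cell cycle genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.118 with an estimated correlation). In EC they differed by -0.69 ± 0.26, a call that ended at 0.266 without EC fresh positive and 0.197 without EC explant positive (camera adjusted p = 8.05e-04). Among the 20 cell cycle genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). In MC they differed by -0.60 ± 0.25 (camera adjusted p = 1.24e-04). Among the 20 cell cycle genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.269 with an estimated correlation). Mesenchymal genes were higher in explant EC by 1.20 ± 0.30, a call that ended at 0.0908 without EC explant negative (camera adjusted p = 1.09e-04). Among the 18 mesenchymal genes, 0 passed over all genes and 2 adjusted over the list alone (adjusted p = 0.264 with an estimated correlation). Interferon response genes were higher in explant MC by 3.31 ± 2.15, and by 1.79 without the block of MC fresh positive (camera adjusted p = 4.16e-06). Among the 16 interferon response genes, 0 passed over all genes and 7 adjusted over the list alone (adjusted p = 0.502 with an estimated correlation).

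**Figure D4:**
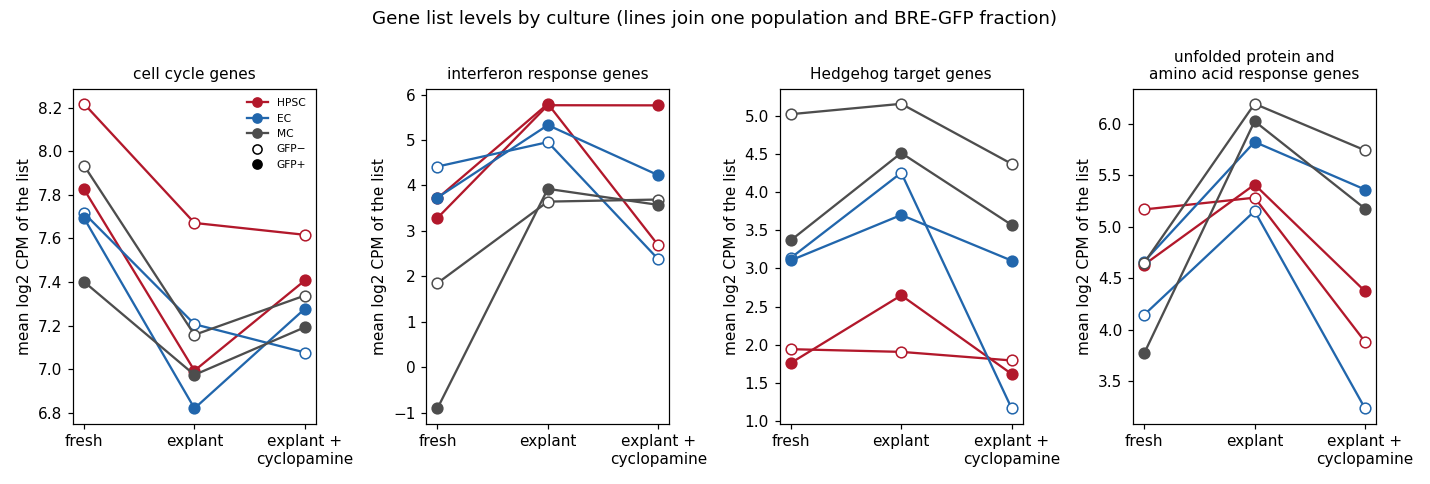
The y axis is the mean log2 CPM of the genes of a list and each line joins the fresh, explant and cyclopamine explant library of 1 population and BRE-GFP fraction, for cell cycle, interferon response, Hedgehog target and unfolded protein response genes from left to right. Red is HPSC, blue EC, grey MC and filled points BRE-GFP positive, cell cycle genes differ by -0.66 ± 0.19 between explant and fresh, and Hedgehog target genes by -1.10 ± 1.03 between cyclopamine and explant.

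Cyclopamine-treated explants had fewer detected genes than untreated ones in 6 of 6 blocks, by 3309 ± 1411 genes (two-sided exact sign-flip test, p = 0.03125, the smallest that 6 blocks allow). Their share of reads at no annotated feature was lower in all 6, by 16.8 ± 4.12 percentage points (exact p = 0.03125, both p assuming independent blocks). Over all populations edgeR called 0 genes between cyclopamine and explant (1319 at an unadjusted p under 0.05). DESeq2 called 172 (12 higher, 160 lower) and limma-voom 819 (123 higher, 696 lower). Hedgehog target genes, which Smoothened activity induces, were lower in 6 of 6 blocks, differing by -1.10 ± 1.03 in mean log2 CPM (-0.70 without the BRE-GFP negative EC block). They were not called against the other genes, many of which were also lower (camera adjusted p = 0.681). Of the 11 Hedgehog target genes, 0 passed over all genes and 1 adjusted over the list alone (adjusted p = 0.961 with an estimated correlation). Gli1, the transcription factor most directly induced by Hedgehog (chromosome 10, 127329882 to 127341974, minus strand), averaged 9.38 ± 10.9 against 17.5 ± 15.3 CPM (cyclopamine first, n = 6 libraries each; log2 fold change -1.39 ± 1.09 (SE), edgeR adjusted p = 0.925). The inhibitor Hhip averaged 4.31 ± 5.72 against 28.3 ± 29.2 CPM and the receptor gene Ptch1 18.99 ± 10.9 against 31.97 ± 22.7 CPM, and neither passed (edgeR adjusted p = 0.55 and 0.987). Aldh1a2, which makes retinoic acid, at 95.2 ± 46.5 against 43.8 ± 52.6 CPM, Fasn, the fatty acid synthase, at 126 ± 30.4 against 52.2 ± 16.8 CPM, and Nucks1 at 357 ± 74.4 against 217 ± 51.4 CPM had the lowest p among higher genes. Rab44, Itgax and Rbm44 had it among lower ones, all 6 at an edgeR adjusted p of 0.358. BMP target genes were not called (camera adjusted p = 0.844), and their mean score differed by -0.54 ± 0.37. The median of their log2 fold changes was -0.61, while the test against other genes pointed up. Cell cycle genes were higher relative to the other genes, with a score difference of 0.18 ± 0.24 (camera adjusted p = 5.64e-04). Of the 20 cell cycle genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.0524 with an estimated correlation). Cholesterol synthesis genes were higher in the same sense (0.09 ± 0.33; 0.19 without the BRE-GFP negative HPSC block, 0.04 without the positive HPSC and -0.00188 without the positive EC block), a call that ended at 0.0797 without EC cyclopamine negative and 0.0611 without HPSC explant positive (camera adjusted p = 0.00405). Of the 18 cholesterol synthesis genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.753 with an estimated correlation). Mesenchymal genes were higher in that sense too (0.06 ± 0.53; 0.12 to 0.19 without 1 of the HPSC blocks or the negative EC block, -0.08 without the positive EC block, -0.01 and -0.02 without the negative and positive MC block), a call that ended at 0.0797 without EC cyclopamine negative, 0.153 without EC cyclopamine positive, 0.0791 without HPSC explant negative and 0.101 without MC explant positive (camera adjusted p = 0.0117). Of the 18 mesenchymal genes, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.753 with an estimated correlation). With the no-feature share as a covariate, the cholesterol and mesenchymal lists pointed down (camera adjusted p = 0.795 and 0.552).

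Within single populations the cyclopamine comparison rested on 2 libraries against 2. In HPSC, edgeR called 0 genes (961 at an unadjusted p under 0.05), DESeq2 405 (27 higher, 378 lower) and limma-voom 0. Without HPSC cyclopamine positive, which leaves the shallowest library of all alone in its arm, edgeR called 612. Lrrc17, at 2.32 ± 0.0754 against 18.1 ± 0.992 CPM, and Aldh1a2, at 42.7 ± 10.5 against 7.81 ± 0.376 CPM, were among the genes of lowest p in HPSC and did not pass. In EC, edgeR called 0 genes (681 at an unadjusted p under 0.05), DESeq2 136 and limma-voom 0, and edgeR called 185 without EC cyclopamine positive. Hbb-y, an embryonic globin gene with close paralogs, averaged 5.47 ± 0.716 against 534 ± 177 CPM and Aldh1a2 112 ± 35.5 against 18.2 ± 0.112 CPM without passing. In MC, edgeR called 0 genes (107 at an unadjusted p under 0.05), DESeq2 0 and limma-voom 1462 (397 higher, 1065 lower). Igfbp5, an insulin-like growth factor binding protein, averaged 1585 ± 46.4 against 522 ± 30.01 CPM there without passing by edgeR. The test of whether the cyclopamine effect differed between BRE-GFP positive and negative cells called 0 genes by edgeR (672 at an unadjusted p under 0.05), 211 by DESeq2 and 1 by limma-voom. EdgeR called 1 without MC cyclopamine negative or MC cyclopamine positive. Samd9l, Prg2, Esam, Csf1r, S100a8 and Angpt2 had the lowest p in that test.

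Single HPSC libraries were also compared, with no replicate check and no test. In fresh HPSC, the BRE-GFP positive library exceeded the negative one in all 18 pan-endothelial genes, with a median log2 ratio of CPM + 5 of 4.33, percentile 100 among 10000 random lists matched on mean expression. Flt4, a VEGF receptor of venous and lymphatic endothelium, stood at 426.9 against 1 CPM, Robo4 at 320.7 against 0 CPM and the laminin gene Lama4 at 802.6 against 1.5 CPM. The macrophage genes Emr1 and Fcrls stood at 7.7 against 434.6 CPM and 12.8 against 446.9 CPM, and the germ cell gene Dppa3 at 0 against 113.1 CPM. In explant HPSC the pan-endothelial median was 2.69 (18 of 18 genes, percentile 100) and the germ cell median -2.19 (percentile 0). Between the cyclopamine and explant libraries of BRE-GFP positive HPSC, pan-endothelial genes had a median of -1.0 (1 of 18 genes higher, percentile 0) and venous genes of -1.34 (2 of 8 genes higher, percentile 0). Hematopoietic transcription factors had a median of 0.75 (17 of 20 genes higher, percentile 100) and myeloid genes of 1.03 (14 of 18 genes higher, percentile 100). Hedgehog target genes had a median of -0.15 (3 of 11 genes higher, percentile 44.4) and BMP target genes of -0.18 (5 of 16 genes higher, percentile 44).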

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

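In this part, the tests of the share of endothelial cells, of a BMP response, of Smoothened inhibition and of Hedgehog target genes in MC alone, the exact sign-flip tests and the tests of differences between populations were chosen after the result was seen.

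In BRE-GFP positive HPSC and EC, pan-endothelial genes were higher in 6 of 6 pairs, by 3.32 ± 1.35, and myeloid (-1.44 ± 1.25) and germ cell genes (-2.87 ± 2.0) lower in 5, both being higher in the cyclopamine HPSC pair. With every library thinned to the shallowest depth the pan-endothelial difference was 3.07 ± 1.32, higher in 6 of 6 pairs, which argues against depth as its source. A lower endothelial share in the BRE-GFP negative gates would lower all 9 lists of other cell types in positive cells only with an unchanged mix. In EC, neural crest genes were higher by 2.34 ± 1.07 in 3 of 3 pairs and myeloid genes differed by -1.97 ± 0.77. These opposite signs, not checked at equal depth, go against an unchanged mix. In HPSC the highest of the 9, mesenchymal, differed by 0.20 ± 0.89 and by 0.71 without the fresh pair. Cell types that did not replace endothelial cells need not fall, so a lower share or another change stays open. A BMP response in the positive cells also stays open, since BMP target genes (0.72 ± 0.75) were higher in the 4 cultured and lower in the 2 fresh pairs.

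Fewer genes were detected in cyclopamine than in explant libraries, and with both libraries of a block at equal depth still in 6 of 6 blocks, which argues against lower sequencing depth. Another candidate is reads from unspliced or genomic sequence that add scattered counts to explant libraries, but the share of counts in genes below the CPM minimum, higher in the explant library in 6 of 6 blocks, largely restates the difference in detected genes and decides nothing. Genes with at least 10 counts were also fewer with cyclopamine in 6 of 6 blocks at equal depth, so scattered counts are not shown to be the whole of it. Effects of cyclopamine or a culture or library batch were not tested apart and stay open.

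Hedgehog target genes were lower with cyclopamine in 6 of 6 blocks, differing by -1.10 ± 1.03 (-0.70 without the BRE-GFP negative EC block; two-sided exact sign-flip p = 0.03125, the smallest possible, and 0.108 adjusted over 31 lists), and 8 other lists were also lower in 6 of 6 blocks. Their difference lay at percentile 13.4 of random lists matched on mean expression, whose median was -0.77, so a loss of low-abundance genes in cyclopamine libraries may account for it over all blocks. In the 2 MC blocks, picked after the result was seen, the difference was -0.87 ± 0.11, at percentile 0.2 of such lists (median -0.15). This goes against that loss in MC but leaves it open. Smoothened inhibition by cyclopamine predicts lower direct targets, and a set of 4 of them was lower in 18 of 24 gene and block combinations. Of 10000 random sets of 4 genes matched on mean expression, 6.1% reached 18 or more (median 14). This was added after the 18 of 24 was seen, so Smoothened inhibition stays open.

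Of 74 groups of 6 libraries, 6 blocks or 9 pairs examined for a single far value, 3 had one, and chance gives about 1 in 20 groups. The 10 most abundant genes took 9.5% of the counts of EC fresh negative, above the other EC libraries. MC fresh positive had 12028 genes detected, fewer than the other MC libraries, and the block of MC fresh positive had a venous score difference to EC of -5.24, below the other 5 blocks.

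Of 93 list differences of the BRE-GFP effect between populations (mean score difference, BRE-GFP positive minus negative, over 3 pairs each), 17 were called by camera, with adjusted p from 3.19e-11 to 0.0489, and 0 with an estimated correlation (adjusted p = 0.209 to 0.81). The effect in HPSC minus that in EC was 1.55 for venous, 1.05 for myeloid (0.47 without the cyclopamine pairs) and -2.30 for neural crest genes. HPSC minus MC gave 3.80 for pan-endothelial, 2.78 for arterial, 2.81 for venous, 2.46 for VEGF, -0.58 for smooth muscle, -0.76 for myeloid, -2.21 for germ cell and -1.20 for neural crest genes. Of these, the last 4 were 0.30, -0.39, -1.09 and -0.01 without the fresh and -1.34, -1.24, -3.73 and -1.93 without the cyclopamine pairs. EC minus MC gave 2.75 for pan-endothelial, 2.10 for arterial, -1.82 for myeloid, -2.27 for germ cell, 2.25 for urogenital and -0.51 for immediate early and heat shock genes (-0.23 without the explant and -0.95 without the cyclopamine pairs). The share of reads at no annotated feature was 16.8 percentage points higher in explant than cyclopamine libraries, in 6 of 6 blocks.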

How the results depend on the processing

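The fits without the library of fewest genes of each population and with the share of reads at no annotated feature as a covariate were chosen after the data were seen. The edgeR counts of genes past the threshold were 52 for HPSC against EC, 413 for MC against EC, 9 for BRE-GFP, 22 for explant, 6 for BRE-GFP within HPSC, 2 for BRE-GFP within EC and 1 for explant within EC, and 0 for the other tests, whose unadjusted counts stand in the report. They depended on the tool and on single libraries. DESeq2 gave 795 for HPSC against EC, 1246 for MC against EC, 371 for BRE-GFP, 484 for explant, 172 for cyclopamine, 929 for BRE-GFP within HPSC, 275 for explant within HPSC, 405 for cyclopamine within HPSC, 426 for BRE-GFP within EC, 119 for explant within EC, 136 for cyclopamine within EC, 5 for BRE-GFP within MC, 66 for explant within MC, 49 for BRE-GFP by population and 211 for cyclopamine by BRE-GFP. Limma-voom gave 570 for HPSC against EC, 1932 for MC against EC, 202 for BRE-GFP, 1270 for explant, 819 for cyclopamine, 136 for BRE-GFP within HPSC, 15 for explant within HPSC, 7 for explant within EC, 102 for BRE-GFP within MC, 13 for explant within MC, 1462 for cyclopamine within MC, 2 for BRE-GFP by population and 1 for cyclopamine by BRE-GFP. Without an expression filter edgeR gave 21 for BRE-GFP, 39 for explant, 96 for BRE-GFP within HPSC, 18 for explant within HPSC, 31 for explant within EC, 2 for cyclopamine within EC, 8 for explant within MC and 1 for BRE-GFP by population, and with the CPM minimum in 6 libraries 0 for BRE-GFP, 11 for explant and 0 for BRE-GFP within EC (801 for BRE-GFP and 673 for BRE-GFP within EC at an unadjusted p under 0.05). The additive model gave 14 for explant. With the no-feature share as a covariate the counts were 5 for HPSC against EC, 0 for BRE-GFP and 0 for explant, and without the 3 libraries of fewest genes 32 for HPSC against EC, 0 for BRE-GFP, 37 for explant, 10 for BRE-GFP within HPSC, 1 for explant within HPSC, 0 for BRE-GFP within EC and 6 for explant within EC, where fewer libraries were fitted. BRE-GFP positive libraries alone gave 7 for explant and negative ones 0 for explant; HPSC libraries alone gave 0 for BRE-GFP within HPSC, and EC libraries alone 0 for BRE-GFP within EC and 0 for explant within EC. With 1 library left out, which leaves its partner in a block unpaired and assumes that a lone library varies like the others, counts ran from 1 to 77 for HPSC against EC, 258 to 492 for MC against EC, 0 to 6 for BRE-GFP, 7 to 39 for explant, 0 to 0 for BRE-GFP within HPSC, 0 to 2 for explant within HPSC, 0 to 612 for cyclopamine within HPSC, 0 to 2 for BRE-GFP within EC, 0 to 0 for explant within EC, 0 to 185 for cyclopamine within EC and 0 to 1 for cyclopamine by BRE-GFP; the libraries and counts are named beside each comparison. Other counts stayed within 1.5 times, including all with RLE size factors and with robust empirical Bayes; apart from fewer libraries or other genes tested, the cause was not tested. Each combination has 1 library, so matching is by the blocks in the models.

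Of 112 list calls, 112 stood with RLE size factors, 107 with prior count 0.5, 58 of 59 in the additive model, 49 of 59 with the covariate, 96 without the 3 libraries of fewest genes, 58 under every library left out, and 11 with an estimated correlation. Those 11 are BMP targets, Hedgehog components, mesenchymal, megakaryocyte and mast cell genes in HPSC against EC, progenitor surface, pan-endothelial, myeloid, megakaryocyte and neural crest genes in MC against EC, and cell cycle genes in explant against fresh. Direction reversed, without a call, for mesenchymal (adjusted p = 0.552) and cholesterol genes (0.795) of the cyclopamine comparison with the covariate, and within MC for erythroid (0.895) and neural crest genes (0.705) of the explant comparison without the 3 libraries. With 1 library left out, adjusted p ran from 3.38e-04 to 0.831 (erythroid genes: explant versus fresh in MC) and from 0.00387 to 0.831 (sympathetic neural crest genes: explant versus fresh in MC). Both reversed without MC fresh positive, at 0.831. The cause was not tested.

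Of 70 named genes that passed, 70 passed with DESeq2, with RLE size factors and without a filter, 68 with limma-voom, 67 with robust empirical Bayes, 46 of 69 with the CPM minimum in 6 libraries, 44 of 61 in the additive model, 30 of 70 without the 3 libraries of fewest genes and 18 of 61 with the covariate, and none of them changed sign in these fits or with 1 library left out. Of 465 single-library list medians, 5 changed sign with a pseudocount of 1 CPM and 21 without TMM scaling, none of them among the 143 in the outer percentiles. Depth limits the cyclopamine comparison in HPSC, where the negative library is the shallowest of all.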

Other observations

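Single-library values in this paragraph and the next have no replicate check or test. Fresh BRE-GFP positive MC had fewer erythroid transcripts than negative MC, with a list median log2 ratio of -3.43 (0 of 12 genes higher, percentile 0), Hbb-bh1, an embryonic globin gene, at 2.2 against 3561.7 CPM and Alas2, the erythroid heme synthesis gene, at 0.2 against 248 CPM. Sympathetic neural crest genes went the other way, at 2.15 (13 of 13 genes higher, percentile 100), with the neuroendocrine genes Resp18 at 113.8 against 0.9 CPM and Cartpt at 54.3 against 0.2 CPM, and stood at 0.92 (13 of 13 genes higher, percentile 100) in the explant and 0.02 (9 of 13 genes higher, percentile 64.1) in the cyclopamine pair. Erythroid genes stood there at 0.15 (7 of 12 genes higher, percentile 84) and -0.72 (3 of 12 genes higher, percentile 0). MC fresh positive stands apart, with 12028 genes detected, the fewest of MC, and a median Spearman correlation of 0.731 with the other libraries. In cyclopamine EC the positive library held cartilage matrix genes, with Matn1 at 761.8 against 0.7 CPM and Epyc at 474.8 against 0.7 CPM.

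Between cyclopamine and explant, MC carried more Ngfr, a neurotrophin receptor, in both fractions, at 68.2 against 6.8 CPM in BRE-GFP negative and 63.4 against 5.1 CPM in positive MC (cyclopamine first). Hedgehog target genes had medians of -0.67 (2 of 11 genes higher, percentile 0) in BRE-GFP negative and -0.43 (2 of 11 genes higher, percentile 0.9) in positive MC.

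Groupings of the same libraries other than the real one, made by swapping libraries within blocks, were fitted to see how often they gave as many genes; all but the BRE-GFP comparison over all populations, for which 100 were drawn, include every split. Only 1 of 32 splits, the real one, gave as many genes for HPSC against EC (52 genes, highest other 0). The same held for MC against EC (413, 20) and explant (22, 5), and 1 of 100 splits for BRE-GFP (9, 0). This argues against chance without excluding it, since 1 split is the fewest possible. For cyclopamine (0 genes, highest other 3) and for BRE-GFP by population, where the population of each pair was permuted within a culture (0 genes, highest other 0), the real count was 0, so 32 of 32 and 36 of 36 splits gave as many by construction, which says nothing about chance. For BRE-GFP within HPSC (6 genes, highest other 0), within EC (2, 0) and within MC (0, 0), and for cyclopamine by BRE-GFP (0, 0), the 4 splits are too few for a share under 0.05.

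Over all populations, the median and mean log2 fold change of each called list had the sign of its camera test. In lists that were not called, at least 1 of the 3 differed in sign from the others for BMP pathway components, VEGF ligands and receptors and cell cycle genes in MC against EC, and for mast cell genes, cholesterol synthesis genes, interferon response genes and unfolded protein response genes between the BRE-GFP fractions. The same held for BMP target genes, BMP pathway components, Hedgehog pathway components, hematopoietic transcription factors, pan-endothelial genes, mesenchymal genes, urogenital epithelium genes and sex-linked expression markers in explant against fresh libraries. It also held for BMP target genes, Hedgehog pathway components, hematopoietic transcription factors, arterial genes, myeloid genes, neural crest genes and urogenital epithelium genes in cyclopamine against explant libraries.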
